A study of Mus musculus with 3 samples.

How the data were processed

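J774A.1 cells, an established mouse macrophage-like line, were kept for 6 h in RPMI medium with 10% fetal bovine serum, in EBSS or in EBSS with 10 µM SB202190, per the labels. The design text can be read as RPMI in all 3 media, and the source names, which give RPMI, EBSS and EBSS with SB202190, were followed. Total RNA was amplified and labelled with Cy5 or Cy3 and hybridised on 3 Agilent 4x44K whole mouse genome arrays of 1 slide. Array 1 held RPMI in Cy5 and EBSS in Cy3, array 2 EBSS in Cy5 and EBSS with SB202190 in Cy3, and array 3 EBSS with SB202190 in Cy5 and RPMI in Cy3, per the labels. Each condition was therefore treated as 1 sample read in both dyes. Whether the 2 channels of a condition came from 1 RNA extract, and whether the cells in EBSS received the solvent of the inhibitor, is not given in the sources used here. As the arrays share a slide and each pairs a different set of conditions, slide and scan could not act as a batch between conditions.

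The arrays were scanned and the spots read with Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. The deposited files give the mean intensity of each spot and the median intensity of its local background in both dyes, without normalization, per the file headers. They also give processed intensities, from which the software had subtracted background and a spatial trend and which it had dye-normalized with linear and lowess steps, per the file headers. The deposited log10 ratio of Cy5 over Cy3 is that of these processed intensities, and it is set to 0 where both channels held surrogate values (31.3% to 34.4% of spots). Deposited marks per spot, of other kinds than a measurement, say whether a spot is well above background, saturated, an outlier or a control, per the file headers. The authors' series table of log2 ratios was set against the scanner values of the same arrays: it holds the mean over spots of log2 Cy5 over Cy3 of the processed intensities, without centring, with medians of -0.0854, -0.0766 and -0.166, so that scale, centring and direction are known.

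From these files, the mean intensities were background-corrected with normexp (offset 50, fitted on all spots) and normalized within arrays by loess with control spots at weight 0, in limma 3.58.1 (R 4.3.3). Control spots (1639 of 45018 per array) and outlier spots (136 to 178 per array) were left out, no spot was saturated, and spots of 1 probe were averaged. Further steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. Of 41174 probes 24375 were named through an accession in a RefSeq table of assembly GRCm38.p6, used for names only, 6301 carried a current symbol, 2426 an older synonym, and 8072 kept the name in the files, which can be old. In total, 49 probes were left out. Positions are those of the probes in the files, on build mm8. A gene was represented by its probe of highest mean intensity. Ratios of other probes are given below for some named genes only, so a value without them does not mean that the probes matched. Of 867 counted genes in EBSS against RPMI, 409 had another measured probe, which had the opposite sign for 22 and a size under 0.5 for 181; of 445 with SB202190 against EBSS these were 208, 16 and 107.

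Log2 ratios were least-squares estimates over the loop of 3 arrays. The technical standard error came from the sum of ratios around the loop, as a robust SD in 30 bins of intensity. The value given for a gene is that of its bin, and the gene's own paths through the loop can differ by more. A gene was counted as higher or lower when its log2 ratio was at least 1 in size, when the array that held both conditions and the path through the other 2 arrays gave the same sign and at least 0.5 each, and when its probe was well above background on both arrays of at least 1 of the compared conditions. These rules, the gene lists, the rule for named genes and 14 alternatives were fixed before the data were examined. With 1 sample per condition no p-value was computed. Lower bounds for genes not well above background in a condition were computed from channel intensities, but exceeded the ratios of the same probes, and are left out.

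The genes named were drawn from the 10 highest and 10 lowest counted genes with a gene symbol for EBSS against RPMI and for SB202190 in EBSS, the 5 highest and 5 lowest for EBSS with SB202190 against RPMI, the 8 genes moved back with the largest smaller change, the 3 members of each list with the largest ratio, and Mapk14, Mapk11, Mapkapk2 and Asns. Some genes that this rule names are not reported here. Further list members were named as examples after their values were seen. The 25 gene lists cover the amino acid and integrated stress response, amino acid transporters, aminoacyl-tRNA synthetases, cholesterol and fatty acid synthesis, autophagy, lysosome, phagocytic receptors, actin remodelling, inflammatory mediators, immediate early genes, the p38 and stress MAP kinase pathway, DNA replication, mitosis, interferon-stimulated genes, ribosomal proteins, ribosome biogenesis, FOXO targets, glycolysis and hypoxia, oxidative stress, chaperones of the endoplasmic reticulum, heat shock proteins, p53 targets and apoptosis, macrophage identity and markers of other cell types. Each list's median was placed among 10000 random lists of the same size matched on intensity, as a description of these arrays, and a list stood apart at or below percentile 2.5 or at or above 97.5.

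The estimates and the counting rule were tested on simulated log2 ratios with normally distributed error of the measured technical size. In these, 200 of 11874 genes were changed for EBSS against RPMI. Background correction, loess and the choice of probe were not run, and errors with wider tails were left out. All 50 genes with a true log2 ratio of 1.5 and all 50 with one of 2.0 were counted, 24 of 50 with one of 1.0 and 0 of 50 with one of 0.5, and 0 of 11674 unchanged genes were counted. Of 200 simulated lists without a shift 11 stood apart, with genes drawn independently, unlike genes that vary together.

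The normexp fit was pulled down by 2 to 11 spots per channel that were darker than their local background, which shrinks the ratios of dim genes. The fitted background mean was -572 in Cy5 of array 1 and from -382 to -113 on arrays 2 and 3. In Cy3 of array 1 it was 5.21, against 116 in a fit without dark spots. These spots thus shifted the RPMI and EBSS channels of array 1 unequally before loess. The setting was kept because it had been fixed, and a fit without these spots was added after seeing the data. The 14 alternatives were no background correction, normexp with offset 0, the scanner software's log ratios, the series table, median centring without loess, equal spread between arrays, 2 other filters on dim probes, each path through the loop alone, the median of all probes of a gene, 2 other size rules, and outlier spots kept. A further 5 gene lists (small nucleolar RNA host genes, tubulins with the gamma-tubulin complex, core histones, the vacuolar proton pump, and folliculin with Rag GTPases) were chosen after the data had been seen, and a list of nonsense-mediated decay factors before its own values were seen. A test of a uniform weakening of the starvation response was replaced after its result was seen, since it set single cultures against technical noise. The tests of array noise and of the EBSS culture alone were also replaced, since the first simulated technical error only and the second left the shared RPMI sample out of account.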

Results

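Gene expression was measured in J774A.1 cells, a mouse macrophage-like line, after 6 h in 1 of 3 media. The media were RPMI medium with 10% fetal bovine serum (RPMI), Earle's Balanced Salt Solution (EBSS), a salt solution with glucose and without amino acids, and EBSS with 10 µM SB202190, an inhibitor of the p38 MAP kinases. RNA of the 3 conditions was compared on 3 two-colour arrays that closed a loop, so that each condition was read on 2 arrays, in Cy5 on 1 and in Cy3 on the other. Each condition was treated as 1 sample, as the labels name 1 source for each. No separate cultures are named, so no test between conditions was made. Every error given for a gene comes from the loop of arrays. It is technical and leaves out the spread between cultures, unless the 2 channels of a condition came from separate ones.

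Between 40.1% and 49.9% of the spots were well above background in a given channel, and 13194 of 27572 genes were well above background nowhere. Over 10777 genes well above background everywhere, the 2 dye channels of a condition correlated across genes at 0.995 to 0.997, and channels of different conditions at 0.945 to 0.971. The sum of log2 ratios around the loop, which is 0 without error, had an SD of 0.287, against 0.863 for unrelated arrays. The ratio from the array that held both conditions and the ratio through the other 2 arrays correlated across genes at 0.881 for EBSS against RPMI, 0.824 for the inhibitor in EBSS and 0.813 for EBSS with SB202190 against RPMI. The median technical standard error of a log2 ratio was 0.108, and the number of arrays limits this precision.

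**Figure D1:**
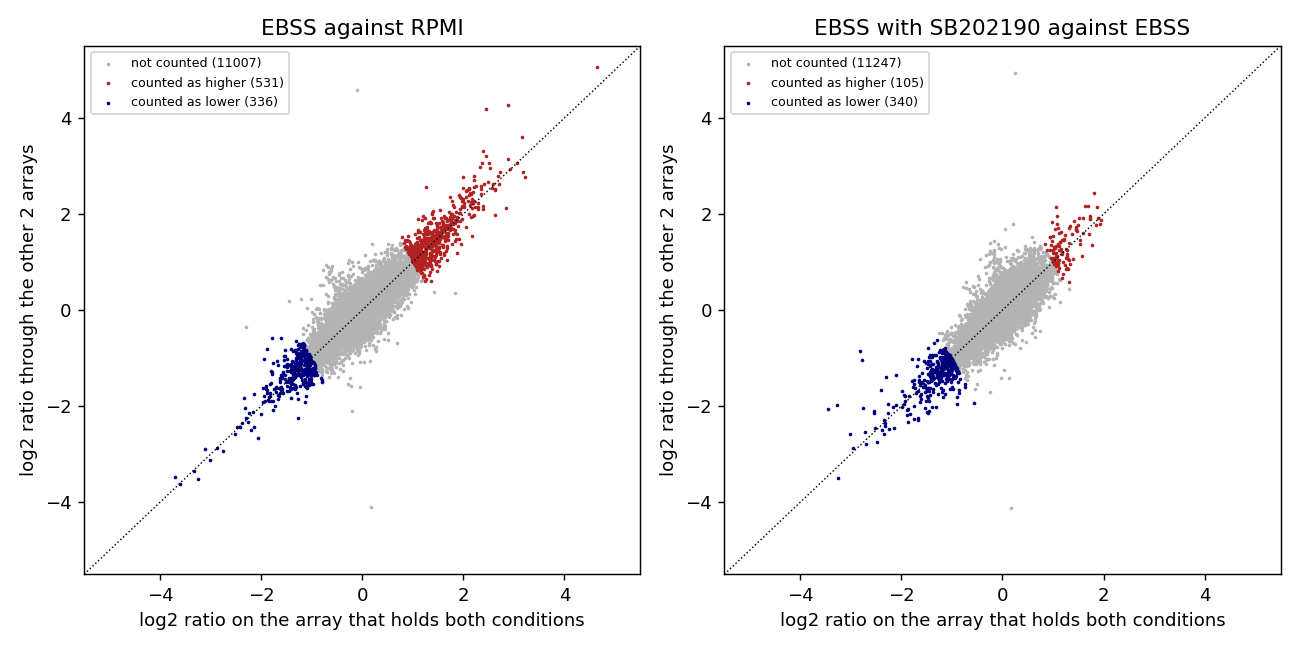
Log2 ratio of each measured gene on the array that held both conditions (horizontal axis) against the ratio through the other 2 arrays (vertical axis), for EBSS against RPMI (left) and EBSS with SB202190 against EBSS (right). Each point is 1 gene. Genes counted as higher are red (531 left, 105 right), genes counted as lower are blue (336 left, 340 right), and the dotted line marks equal values.

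EBSS was set against RPMI to describe the response to a salt solution without amino acids, for which the labels name no serum. As whole media were compared, effects of amino acids, of serum and of other ingredients of RPMI cannot be told apart. In total, 531 genes were counted as higher and 336 as lower in EBSS among 11874 measured genes. The highest was Ndrg1, a stress- and hypoxia-inducible gene, with a log2 ratio of 4.79 ± 0.13 (technical SE), or 27.6-fold. Ddit3, which encodes the stress transcription factor CHOP, rose by 3.32 ± 0.12 and Trib3, a pseudokinase induced by the same response, by 3.07 ± 0.19. Among the lowest were Dusp6, a phosphatase of ERK kinases, at -3.61 ± 0.12, and Ccnd1, which encodes cyclin D1, at -3.03 ± 0.11.

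The other genes with the largest rise in EBSS were the inflammatory caspase gene Casp4 (3.08), the pro-apoptotic Bbc3 (3.07), Hbp1 (2.97), Gadd45a (2.94), Ppp1r15a (2.78), Nupr1 (2.71) and Sqstm1 (2.71), which encodes an autophagy receptor. The lowest gene was P2ry6, a receptor for extracellular nucleotides, at -3.63 ± 0.11. It was followed, besides Dusp6 and Ccnd1, by Id1 (-3.34), Arl4c (-3.34), Sapcd2 (-3.06), Elk3 (-2.87), Lpar6 (-2.82), Tnfaip8l1 (-2.46) and Slc16a6 (-2.43). The Ndrg1 probe lies on chromosome 15 from 66759164 to 66759223 and the Dusp6 probe on chromosome 10 from 98697039 to 98697098 (mm8). The P2ry6 probe lies on chromosome 7 from 100811722 to 100811781 of that build, and where the probes lie within exons was not analysed here. Other probes of the same genes gave smaller ratios for Arl4c (-0.80), Hbp1 (1.35), Lpar6 (-1.60) and Slc16a6 (-0.25, above background in RPMI only).

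Among the gene lists, the amino acid response and integrated stress response moved most. Its median log2 ratio was 1.64, above all 10000 random lists of the same size and intensity (percentile 100), with 16 of 25 measured members higher and 0 lower. Sesn2 (2.59), Gdf15 (2.25), Atf3 (2.17) and Atf4 (1.64) rose, and the asparagine synthetase gene Asns lay at 0.96 ± 0.19, short of the size required. Amino acid transporters had a median of 0.47 (percentile 100), or 0.97 with the scanner software's log ratios. Of 18 transporters 5 rose, among them Slc38a2 (2.07, with other probes from -0.10 to 1.29), Slc6a9 (1.97) and Slc3a2 (1.34). Of the 20 aminoacyl-tRNA synthetases 6 rose, led by Aars (1.25), Rars (1.22) and Nars (1.19), and none was counted as lower (median 0.74, percentile 100).

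Autophagy genes had a median of 0.41 (percentile 100), and 10 of 30 rose, including Atg12 (2.25), Rb1cc1 (2.06, with other probes from 0.07 to 1.66), Gabarapl1 (1.92) and Ulk1 (1.38). Of 31 lysosomal genes 5 rose (median 0.35, percentile 99.96). These were the proton pump subunits Atp6v1d (1.76), Atp6v1a (1.46), Atp6v1h (1.41) and Atp6v0d1 (1.36), and the galactosidase gene Gla. Among FOXO targets and nutrient deprivation genes, 6 of 15 rose, such as Flcn (2.60), Ccng2 (2.38) and Txnip (1.95), and Sesn1 fell to -1.28. Their median was 0.37 (percentile 99.7, or within the random range without a filter on dim probes), or 0.81 with the scanner software's log ratios. Cytokines, chemokines and other mediators had a median of 0.39 (percentile 100), with Il1rn (2.24, with 0.78 for its other probe), Ccl3 (2.22), Csf1 (1.54) and Cxcl2 (1.29) as the 4 of 27 that rose.

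In 6 lists the median was low in EBSS relative to all measured genes, whose own median was 0.81 with median centring in place of loess. DNA replication genes had a median of -0.41 (percentile 0), with Ccne1 (-1.52, with -0.63 for its other probe) and Tk1 (-1.49) the 2 of 35 that fell. Mitosis genes had one of -0.45 (percentile 0), with Ccna2 (-1.83), Birc5 (-1.43) and Kif20a (-1.04, or 0.16 with median centring) the 3 of 33 that fell. With median centring these medians were 0.81 for DNA replication and 0.57 for mitosis, still at percentiles 0.06 and 0 of random lists of the same intensity. Of 27 macrophage identity genes 4 fell, among them Irf8 (-2.01), C1qa (-1.30) and Cx3cr1, which was not well above background in EBSS, and the median was -0.32 (percentile 0.095), or 0.68 with median centring (percentile 0.89). Oxidative stress genes had a median of -0.41 (percentile 0.01), with Osgin1 (-1.43, with -0.50 and -0.12 for its other probes), Srxn1 (-1.09) and Pgd (-1.06) the 3 of 25 that fell. With median centring that median was 0.81 (percentile 0.14), and Srxn1 (0.14) and Pgd (0.24) were positive. Immediate early and serum response genes went both ways, with 4 of 28 higher, such as Klf4 (2.20) and Dusp1 (1.69), and 6 lower, such as Fos (-2.27) and Dusp2 (-1.68), around a median of -0.19 (percentile 1.65) that was 0.79 with median centring (percentile 16.0), and within the random range with equal spread between arrays (percentile 29.2). For interferon-stimulated genes the median was -0.15 (percentile 1.53) and 1 of 31, Igtp (-1.13), fell. Their median with median centring was 0.45 (percentile 0.73), and the list lay within the random range when the scanner software's log ratios were used (percentile 5.39).

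In the setting used here, the other lists lay within the range of random lists in EBSS. With the scanner software's log ratios and with median centring this did not hold for the cholesterol and the fatty acid list, which stood low (percentiles 1.29 and 1.85 with median centring, at medians of 0.75 and 0.61), and for the p38 list, which stood high. Phagocytic and pattern recognition receptors had a median of 0.11, with Tlr4 (1.36) higher and Tlr2 (-1.41) lower among 32. In the actin remodelling list Coro1a (-1.11) was the 1 of 33 counted, and its ratio was 0.36 with median centring. In the p38 and stress MAP kinase list (median 0.12) 4 of 31 rose, Gadd45a among them with Gadd45b (1.83), Mknk1 (1.81) and Mapkapk3, and the p38 genes themselves had ratios of -0.91 ± 0.13 (Mapk14) and 0.07 ± 0.08 (Mapk11), with 0.12 ± 0.19 for their substrate Mapkapk2. The p53 and apoptosis list (median -0.03) held 5 of 25 that rose, with Plk2 (2.25), Mdm2 (1.87) and Pmaip1 (1.38) beside Bbc3. Glycolysis and hypoxia genes (median -0.20) held 4 of 27 higher, including Hk2 (1.31) and Kdm3a (1.29, with 0.37 and 0.04 for its other probes), and 2 lower, Pfkfb4 (-1.25) and Hk1 (-1.04).

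The 23 cholesterol genes had a median of -0.20. In the fatty acid and liver X receptor list (median -0.22) Abcg1 rose (1.76), and Fasn (-1.61, with 0.03 for its other probe) and Scd2 (-1.22, or 0.13 with median centring) fell among 14. Chaperones of the endoplasmic reticulum had a median of -0.09, with Herpud1 (2.31) and Dnajb9 (2.08) higher and Ssr1 (-1.27, with -0.52 and -0.08 for its other probes) lower among 25. Of 16 heat shock proteins (median -0.28) Hspa9 rose (1.21). None of the 59 ribosomal protein genes was counted (median -0.14), and in ribosome biogenesis (median -0.03) 2 of 36 fell, Ebna1bp2 (-1.30) and Ppan (-1.22). Of the markers of other cell types 28 were on the array and 2 were measured, Hba-a1 (0.03) and S100a8 (-0.38), so that no median was taken.

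For EBSS against RPMI, the scanner software's log ratios called 962 genes higher and 1094 lower, so that higher calls were 46.8% and not 61.3% of all calls, and 531 and 327 of the counted genes were among them. With median centring in place of loess, 4252 genes were higher and 23 lower.

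SB202190 in EBSS was set against EBSS alone to describe what differed with the inhibitor during starvation. An effect of p38 cannot be told apart from one of other targets of SB202190 or from a difference between single cultures. In all, 105 genes were counted as higher and 340 as lower with SB202190 among 11692 measured genes. The lowest were Rgs1 (-3.34 ± 0.10) and Rgs2 (-2.84 ± 0.19), regulators of G protein signalling, and Dusp1 (-2.92 ± 0.12), a phosphatase that inactivates p38 and JNK kinases. Ndrg1, the highest gene of EBSS, fell by 2.87 with SB202190. Cytokine and chemokine genes had a median of -0.79, or -1.51 with the scanner software's log ratios, with 9 of 27 members lower and 2 higher.

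**Figure D2:**
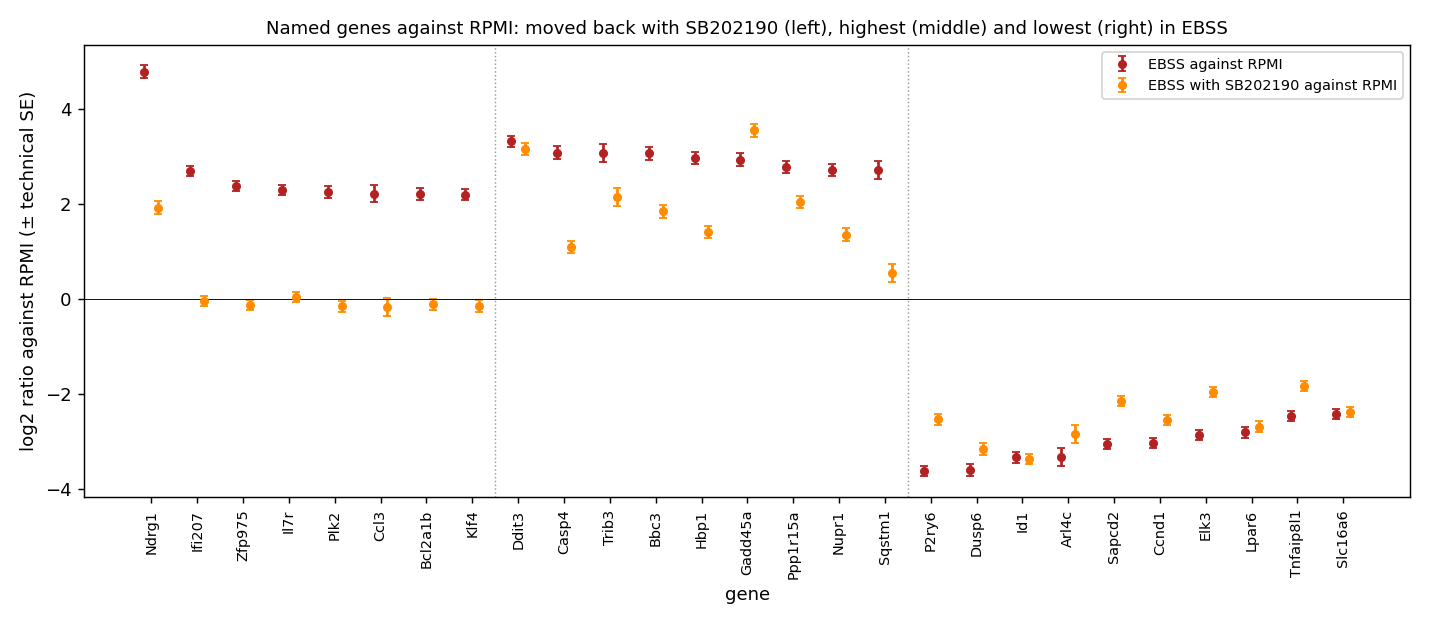
Log2 ratio against RPMI (vertical axis) of genes in EBSS (red) and in EBSS with SB202190 (orange), with the technical standard error as bars. The left block holds the 8 moved-back genes of largest size, in which the ratio was near 0 with SB202190 except for Ndrg1 (1.92); the middle block holds the highest and the right block the lowest genes in EBSS, where values with SB202190 stayed on the same side of 0.

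The other genes that fell most with SB202190 were Ifi207 (-2.73), Lrp12 (-2.65), the fatty acid carrier gene Fabp4 (-2.58), Zfp975 (-2.51), Ptpn14 (-2.43) and Zeb2 (-2.42). Those that rose most were Cbx8 (2.02 ± 0.11), a Polycomb protein gene, Angptl4 (1.97), Phlda3 (1.93), Zfp251 (1.90), Pstk (1.88), Fbxo31 (1.85), Mlycd (1.83), Atp23 (1.81), Nfkbiz (1.81) and Snhg5 (1.79). The Rgs1 probe lies on chromosome 1 from 146007050 to 146007109 and the Cbx8 probe on chromosome 11 from 118852429 to 118852488 (mm8). Other probes of the same genes gave smaller ratios for Cbx8 (0.31), Rgs2 (-0.65), Atp23 (1.11) and Zeb2 (-1.81 and -0.39). The remaining probes of Zeb2, Zfp251, Pstk, Zfp975 and Ptpn14, and 1 of the 2 other probes of Fabp4 (the second gave -2.21), were dim in at least 1 condition and gave ratios from -0.19 to 0.03. Mapk14, which encodes the p38α target of the inhibitor, rose by 1.19 ± 0.13, while Mapk11 was at 0.02 ± 0.08 and Mapkapk2 at 0.28 ± 0.19.

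Among inflammatory mediators (percentile 0), Ccl3 (-2.39), Plau (-2.33, with -0.69 for its other probe), Cxcl10 (-2.32) and Ccl2 (-2.16) fell, and Nfkbiz (1.81) and Nfkbia (1.43), both inhibitor-of-NF-κB family genes, rose. Of 31 phagocytic and pattern recognition receptors 5 fell, Tlr4 with Clec4d (-1.96), C3ar1 (-1.60), Cd14 (-1.55) and Fcgr1 (-1.31), and the median was -0.20 (percentile 0.06). The amino acid and integrated stress response list had a median of -0.75 (percentile 0), and 8 of 25 fell, led by Atf5 (-1.89), Gdf15 (-1.86), Chac1 (-1.41) and Nupr1 (-1.36), whereas Ddit3 was at -0.15 and Asns at -0.83. Synthetases had a median of -0.46 (percentile 0.01) with Aars (-1.22) the 1 of 20 that fell, and transporters one of -0.20 (percentile 1.67) with Slc38a2 (-1.13) and Slc6a9 (-1.02) lower among 16. The transporters lay within the random range with equal spread between arrays (percentile 2.94), on the array that held both conditions alone and with the median of all probes. As EBSS is shared, 3 unrelated cultures of equal spread would return 0.5 of a list's median in EBSS against RPMI, with opposite sign. For the amino acid list (1.64 in EBSS) and transporters (0.47) the medians with SB202190 did not exceed that size. These medians alone therefore do not show an effect of the inhibitor. For inflammatory mediators (0.39 in EBSS), receptors (0.11) and synthetases (0.74) they were larger than that.

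Autophagy genes had a median of -0.16 (percentile 2.15), and Sqstm1 (-2.16), Gabarapl1 (-1.35) and Atg13 (-1.24) fell among 29. Of 31 lysosomal genes 5 fell, Atp6v1a (-1.53), Atp6v1h (-1.31), Atp6v1d (-1.19), Gla (-1.01) and Atp6v1b2 (-1.01), with a median of -0.17 (percentile 0.855). Mitosis genes had a median of -0.26 (percentile 0.1, or 2.73 and within the random range with median centring), and Ccnb1 (-1.33), Prc1 (-1.29), Plk1 (-1.15) and Aurka (-1.09) fell among 33. Higher medians were found for DNA replication (0.20, percentile 98.8), where Tk1 (1.13) rose, and for glycolysis and hypoxia genes (0.24, percentile 99.8), where Ndrg1 was the 1 of 27 counted. With median centring, where all measured genes had a median of -0.45, these 2 medians were -0.54 and -0.46 and within the random range (percentiles 97.4 and 94.6). Both lists also lay within it on the array that held both conditions alone and on the other 2 arrays alone, and glycolysis genes with the scanner software's log ratios. For autophagy (0.41 in EBSS against RPMI), lysosomal (0.35) and DNA replication genes (-0.41), the medians with SB202190 did not exceed 0.5 of these in size. The shared EBSS sample alone could give them. For glycolysis genes (-0.20 in EBSS) the median was larger than that, and mitosis genes (-0.45) had gone the same way in both comparisons.

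Lists within the random range in the setting used here also held counted genes. With the scanner software's log ratios, cholesterol, fatty acid (percentile 98.2) and oxidative stress genes stood high among random lists and macrophage identity genes low (percentile 2.32), while with median centring the medians of the first 3 were -0.43, -0.40 and -0.51, where all measured genes lay at -0.45. Among random lists of the same intensity, oxidative stress genes still stood high there, and cholesterol (percentile 96.7) and fatty acid genes (89.4) did not. Immediate early genes had a median of -0.09 and 8 of 29 fell, among them Klf4 (-2.35), Junb (-1.68) and Myc (-1.21) with Dusp1. In the p38 and stress MAP kinase list Gadd45g (1.28) rose with Mapk14, and Mapkapk3 (-1.17) fell. Metallothioneins Mt1 (1.34, with 0.22 for its other probe) and Mt2 (1.27) rose and Hmox1 (-1.68) fell in the oxidative stress list. Rsad2 (-1.66, with -0.82 and -0.52 for its other probes) fell and Irf1 (1.06, with 0.27 for its other probe) rose among interferon-stimulated genes. Macrophage identity genes had a median of -0.08. Abcg1 (-1.86) fell, and Dhcr7 (1.06) and Fasn (1.00, with 0.10 for its other probe) rose, among lipid genes. Plk2 (-2.41), Mdm2 (-1.49) and Bbc3 (-1.22) fell in the p53 list, Fbxo32 (-1.08) and Flcn (-1.02) among FOXO targets, Hspa9 (-1.37) among heat shock proteins, Dnajb9 (-1.22) among chaperones and Wipf1 (-1.02, with -0.25 for its other probe) in the actin list. No ribosomal protein or ribosome biogenesis gene was counted.

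For SB202190 in EBSS, the scanner software's log ratios called 782 genes higher and 772 lower, a share of 50.3% higher against 23.6%, with 103 and 339 of the counted genes among them. With median centring 18 genes were higher and 769 lower.

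The direction of change with SB202190 was often opposite to that of EBSS. Of the 531 genes higher in EBSS, 192 (36.2%) were lower with SB202190, and of the 336 lower genes 46 (13.7%) were higher. These numbers depend on the processing: with the scanner software's log ratios 415 of 962 and 399 of 1094 genes moved back, and with median centring 675 and 0. The 8 with the largest moves were Ndrg1 (4.79 in EBSS, then -2.87), Ifi207 (2.68, then -2.73), Zfp975 (2.38, then -2.51), the interleukin 7 receptor gene Il7r (2.29, then -2.25), Plk2 (2.25, then -2.41), Ccl3 (2.22, then -2.39), Bcl2a1b (2.21, then -2.32) and Klf4 (2.20, then -2.35). Of the other probes of Il7r 1 gave 0.80 and -0.66, and 1 that was dim outside EBSS gave 0.01 and -0.03. Those of Zfp975 were dim and near 0. Independent lists of these sizes would share 15.7 and 3.05 genes, and simulated loops with array error alone gave 0. As both comparisons use the EBSS sample, its error enters both with opposite signs. With the changes taken from separate arrays, 202 of 533 and 47 of 359 genes moved back, which leaves out shared array error but not the shared EBSS culture. Genes would also move back among 3 unrelated cultures of equal spread, by 0.5 of their ratios. Independent lists are therefore no standard for an effect of the inhibitor. The medians with SB202190 against EBSS were -0.83 over the 531 genes and 0.46 over the 336, against 1.36 and -1.24 in EBSS. The log2 ratios of the comparisons correlated at -0.622 across 11532 genes (covariance -0.148), against -0.499 (covariance -0.00686) in simulated loops without effects, and genes are not independent of each other.

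EBSS with SB202190 was set against RPMI to show what remained of the starvation response under the inhibitor. Altogether, 176 genes were counted as higher and 287 as lower among 11863. The highest were Snhg5 (3.82 ± 0.13), a host transcript of small nucleolar RNAs, Gadd45a (3.55), Ddit3 (3.16), Zfas1 (3.02) and Snhg16 (2.58). Among the lowest were the chemokine gene Ccl2 (-3.81 ± 0.19), Id1 (-3.38), Dusp6 (-3.16) and Skil (-2.89). The Snhg5 probe lies on chromosome 9 from 88318978 to 88319037 and the Ccl2 probe on chromosome 11 from 81853343 to 81853402 (mm8). For Ccl2 the array that held both conditions gave -3.15 and the other path -5.11, and the other probe of Skil gave -1.15.

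Of the 531 genes higher in EBSS, 120 were also counted as higher with SB202190 against RPMI and 4 as lower, and their median was 1.36 in EBSS and 0.56 with SB202190. Of the 336 lower genes 141 were also lower and 0 higher, with medians of -1.24 and -0.83. As RPMI is shared, 3 unrelated cultures of equal spread would carry 0.5 of these ratios over, 0.68 and -0.62. The amino acid and integrated stress response list had a median of 0.53 (percentile 100), with 7 of 25 higher, such as Trib3 (2.14), Ppp1r15a (2.04) and Sesn2 (1.86), and Cebpb (-1.02) lower. In EBSS its median was 1.64, and unrelated cultures would carry over 0.5 of that, which is more than 0.53. The list median alone therefore does not show that this response remained. Autophagy genes had a median of 0.32 (percentile 100), and 5 of 30 were higher, including Ulk1 (1.41) and Atg12 (1.38). FOXO targets had one of 0.46 (percentile 100), with Tsc22d3 (2.22), Txnip (1.97), Ccng2 (1.89) and Flcn (1.58) the 4 of 15 counted as higher. Lysosomal genes (0.24, percentile 99.98) and synthetases (median 0.22, percentile 99.3) held no counted member. For synthetases the median was also under 0.5 of the 0.74 in EBSS. In the p38 and stress MAP kinase list (0.20, percentile 99.7) 5 of 31 were higher, including Gadd45b (2.48) and Gadd45g (1.35), and Mef2c (-1.02) was lower. The synthetases and the p38 list lay within the random range with equal spread between arrays and on the array that held both conditions alone.

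Mitosis genes lay lowest (median -0.68, percentile 0), with 10 of 33 lower, led by Plk1 (-2.14), Ccnb1 (-1.57) and Aurka (-1.36). Lower medians were also found for macrophage identity (-0.29, percentile 0), where C1qa (-1.31), Irf8 (-1.07) and Cebpa (-1.01) were among those that fell, for phagocytic receptors (-0.26, percentile 0.03), where Cd14 (-1.94), Clec4d (-1.81), C3ar1 (-1.40) and Fcgr1 (-1.38) fell, and for immediate early genes (-0.26, percentile 0.02), where Fos (-2.78), Ccnd1 (-2.55) and Junb (-2.16) fell and Ier5 (1.13) rose. Inflammatory mediators had a median of -0.19 (percentile 0.3), with Ccl4 (-2.01), Cxcl10 (-1.93) and Plau (-1.82) among 8 of 27 lower and Nfkbiz (2.43) higher. DNA replication genes had a median of -0.19 (percentile 0.175), interferon-stimulated genes one of -0.21 (percentile 0.12) with Irgm1 (-1.49) and Igtp (-1.29) lower, and oxidative stress genes one of -0.18 (percentile 0.47) with Hmox1 (-1.48) and Srxn1 (-1.37) lower and Mt2 (1.75) higher. With median centring, where the median of all measured genes was 0.34, these medians were 0.082 for macrophage identity, 0.11 for phagocytic receptors, 0.026 for immediate early genes, 0.18 for mediators, 0.29 for DNA replication, 0.012 for interferon-stimulated and 0.36 for oxidative stress genes, and all of these lists but oxidative stress still stood low among random lists of the same intensity. Oxidative stress genes also lay within the random range without background correction (percentile 4.54) and on the array that held both conditions alone, and DNA replication genes on the other 2 arrays alone. For each of these lists the median was also smaller in size than 0.5 of the -0.41 in EBSS against RPMI. The shared RPMI sample alone could carry that over. Transporters (0.05), cholesterol genes (0.01), fatty acid genes (-0.18), the actin list (-0.07), ribosomal proteins (0.07), ribosome biogenesis (0.02), glycolysis (0.04), chaperones (0.08), heat shock proteins (-0.03) and the p53 list (0.02) lay within the random range in the setting used here. Under other settings, ribosomal proteins stood high without background correction (percentile 99.7), with normexp fitted without dark spots (99.3) and with median centring (99.8), against a median of -0.02 with equal spread between arrays. Glycolysis stood high (98.1) and the actin list low with median centring, at medians of 0.59 and 0.33, and chaperones stood high with equal spread (97.7). The scanner software's log ratios called 474 genes higher, with 62.0% of all calls lower, and the 176 and 287 counted genes were among its calls. With median centring 152 genes were higher and 90 lower, and with equal spread between arrays 84 and 160.

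**Figure D3:**
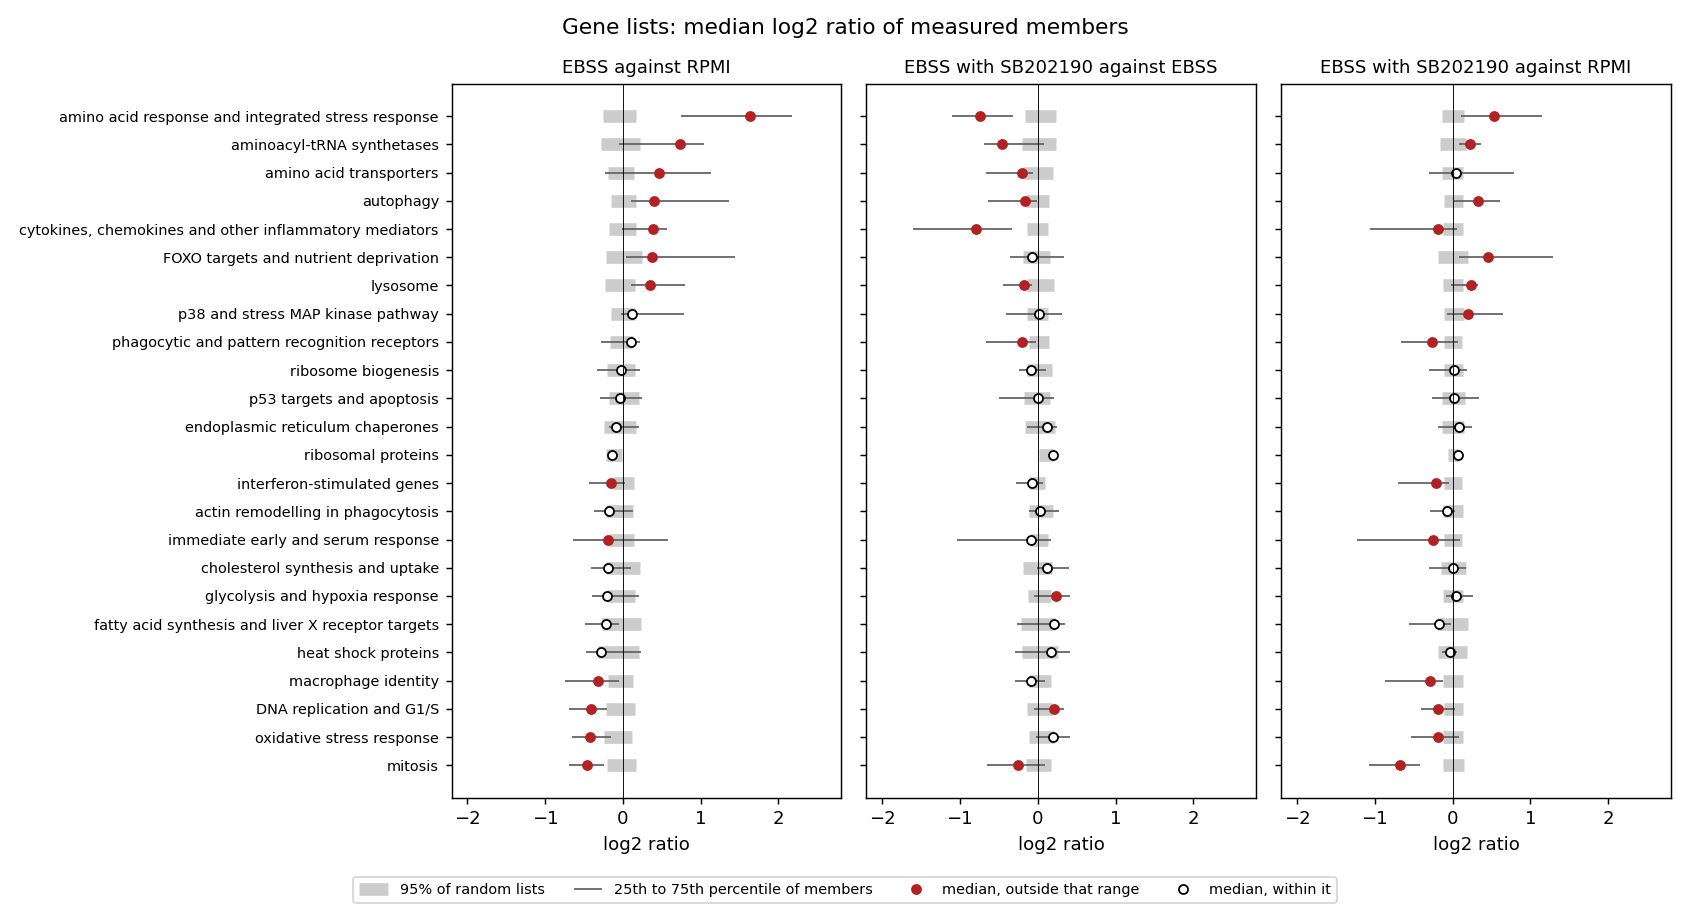
Median log2 ratio (horizontal axis) of the measured members of each gene list (vertical axis) in the 3 comparisons; grey bars hold 95% of random lists, thin lines run from the 25th to the 75th percentile of members, and filled points lie outside the grey bars, as the amino acid response list does at 1.64, -0.75 and 0.53. With median centring the 6 filled low medians of EBSS against RPMI were 0.45 to 0.81, those of EBSS with SB202190 against RPMI 0.012 to 0.36 except for mitosis, and the filled high medians of DNA replication and glycolysis in the comparison with EBSS -0.54 and -0.46, where the median of all measured genes was 0.81, 0.34 and -0.45.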

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

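The tests of background correction and of spike-in amounts were chosen only after the result was seen. The spike-in control spots, which the comparisons do not use, held a signal where equal amounts would give 0. In the scanner software's log ratios all 10 spike-in probes (320 spots) were brighter in EBSS than in RPMI, with a median log2 ratio of 0.495 (range 0.402 to 0.584, or 1.41-fold), and the median was -0.21 for EBSS with SB202190 against EBSS and 0.31 against RPMI. After normexp and loess these medians were 0.44, -0.20 and 0.23. The normexp and loess steps used here are argued against as the source, since the scanner software's log ratios, made without them, held a mean shift of 0.499 (SE 0.0190 over the 10 probes). The probes share 1 tube per condition and dye, so this SE leaves out the spread between tubes. The software's own background and lowess steps were not tested. Unequal spike-in amounts between tubes stay open: the shift had an SD of only 0.0602 over the probes, as a tube difference would give, but with 1 tube per condition and dye it cannot be told apart from a lower share of messenger RNA in the total RNA of cells in EBSS.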

How the results depend on the processing

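The fit of normexp without dark spots was the only alternative chosen after the results were seen. No paired analysis was made because each condition was treated as 1 sample. No gene counted as higher or lower was counted in the opposite direction under any of the 15 alternatives. Of 867 counted genes in EBSS against RPMI, 858 were also counted with the scanner software's log ratios, 855 with normexp fitted without dark spots, 799 with equal spread between arrays, 568 with the median of all probes and 554 with median centring. Of 445 with SB202190 against EBSS these were 442, 444, 439, 267 and 352, and of 463 with SB202190 against RPMI 463, 460, 242, 318 and 220. Outlier spots kept and no filter on dim probes kept all of these calls, and the latter added 0. Neither result shows robustness. The first setting still left the 49 flagged probes out, and lifting a filter cannot remove a call. How far the normexp fit shrank the ratios of the 13194 of 27572 genes well above background nowhere is not given here. Over the measured genes, ratios were larger with normexp fitted without dark spots (slopes of 1.20, 1.26 and 1.20 in the 3 comparisons). They were also larger with the scanner software's log ratios (1.35, 1.42 and 1.38).

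Counts of genes moved by over 1.5 times under these settings. For the size rules and the normexp fit the cause lies in their construction, and for the other settings the cause was not tested. For EBSS against RPMI, genes higher numbered 962 with the scanner software's log ratios or the series table, 4252 with median centring, 345 with the median of all probes, 1225 with a log2 ratio of at least 0.6 and 2272 with 3 technical standard errors. Genes lower in EBSS against RPMI numbered 541 without background correction, 1094 with the scanner software's log ratios or the series table, 23 with median centring, 691 with normexp fitted without dark spots, 1015 at 0.6 and 2126 at 3 standard errors. For EBSS with SB202190 against EBSS, genes higher numbered 244 without background correction, 782 with the scanner software's log ratios or the series table, 18 with median centring, 260 with equal spread, 356 with normexp fitted without dark spots, 204 on the other 2 arrays alone, 65 with the median of all probes, 558 at 0.6 and 1541 at 3 standard errors. Genes lower numbered 772 with the scanner software's log ratios or the series table, 769 with median centring, 619 with equal spread, 600 with normexp fitted without dark spots, 208 with the median of all probes, 992 at 0.6 and 1932 at 3 standard errors. For EBSS with SB202190 against RPMI, genes higher numbered 474 with the scanner software's log ratios or the series table, 84 with equal spread, 288 with normexp fitted without dark spots, 117 with the median of all probes, 598 at 0.6 and 1580 at 3 standard errors, and genes lower 7.7e+02 with the scanner software's log ratios or the series table, 160 with equal spread, 498 with normexp fitted without dark spots, 90 with median centring, 836 at 0.6 and 1824 at 3 standard errors.

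Genes moved back from higher in EBSS to lower with SB202190 numbered 415 with the scanner software's log ratios or the series table, 675 with median centring, 409 with equal spread, 332 with normexp fitted without dark spots, 116 with the median of all probes, 602 at 0.6 and 1254 at 3 standard errors. From lower to higher these were 399, 0, 160, 153, 30, 288 and 827, and 101 without background correction. Higher calls were 61.3% of calls in EBSS against RPMI and 23.6% with SB202190 against EBSS, 46.8% and 50.3% with the scanner software's log ratios, and 52.3% and 37.2% with normexp fitted without dark spots.

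Among lists that stood apart and named genes that were counted, directions reversed with median centring alone, Zfp975 aside. Median centring set each array on the median of its spots, dim ones included, and left the measured genes at medians of 0.81, -0.45 and 0.34. It used the same normexp fit, whose background mean differed between channels of an array (-572 in Cy5 and 5.21 in Cy3 of array 1). Without loess, such a difference stays in the ratios of dim spots, on which the arrays were centred. How much of the shift of the measured genes came from it was not tested. For EBSS against RPMI the list medians were then 0.81 (DNA replication), 0.79 (immediate early), 0.45 (interferon-stimulated), 0.68 (macrophage identity), 0.57 (mitosis) and 0.81 (oxidative stress), and Coro1a was at 0.36, Kif20a at 0.16, Pgd at 0.24, Scd2 at 0.13 and Srxn1 at 0.14. For SB202190 against EBSS they were -0.54 (DNA replication) and -0.46 (glycolysis and hypoxia). For SB202190 in EBSS against RPMI they were 0.29 (DNA replication), 0.18 (inflammatory mediators), 0.026 (immediate early), 0.012 (interferon-stimulated), 0.082 (macrophage identity), 0.36 (oxidative stress) and 0.11 (phagocytic receptors). Among random lists of the same intensity, 12 of 13, 7 of 10 and 13 of 14 of the lists that stood apart still did so on the same side with median centring (lost were immediate early genes, then DNA replication, mitosis and glycolysis, then oxidative stress). Relative to all measured genes the sign changed for 1 of 13, 2 of 10 and 1 of 14 lists that stood apart, and for 0 with the scanner software's log ratios, equal spread, no background correction or normexp fitted without dark spots. With the median of all probes Zfp975 with SB202190 against EBSS went from -2.51 to 0, as its other probes were dim. Of the 13, 10 and 14 lists that stood apart, 12, 9 and 14 did so with the scanner software's log ratios (without interferon-stimulated genes and glycolysis), and 12, 9 and 12 with equal spread (without immediate early genes, transporters, and synthetases with the p38 list). On the array that held both conditions alone 11, 7 and 11 did, and on the other 2 arrays alone 12, 8 and 13. Lost under 2 or more of these 4 settings were immediate early and interferon-stimulated genes in EBSS against RPMI, transporters, DNA replication and glycolysis with SB202190 against EBSS, and synthetases and the p38 list with SB202190 against RPMI. Without a filter on dim probes, FOXO targets and immediate early genes in EBSS against RPMI lay within the random range, and with the median of all probes immediate early genes, transporters and the p38 list did, 1 in each comparison.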

Other observations

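The 5 gene groups described here and the tests on moved-back genes were chosen only after the result was seen. Host genes of small nucleolar RNAs were high in EBSS with SB202190 against RPMI, with a median log2 ratio of 1.25 over 16 genes (percentile 100) and 9 higher, including Snhg5 (3.82), Zfas1 (3.02), Snhg16 (2.58) and Gas5 (2.46). In EBSS against RPMI 7 rose (median 0.77, percentile 100), and with SB202190 against EBSS Snhg5 (1.79) and Snhg17 (1.59) rose and Eif4a1 (-1.07) fell around a median of 0.37 (percentile 99.9) that was -0.20 with median centring, where all measured genes lay at -0.45. Of 19 genes of tubulins and the gamma-tubulin complex 10 fell in EBSS, such as Tubb4b (-1.87), Tuba3a (-1.43) and Tubb2a (-1.38), and none of the 5 complex genes Tubgcp2 to Tubgcp6 was counted. The median was -1.01 (percentile 0), or 0.29 with median centring, where all measured genes lay at 0.81 and 0 of the 19 were lower and 1 higher. With SB202190 against EBSS, Tubb4b (1.27), Tubb2a (1.18), Tubb5 (1.14) and Tubb6 (1.08) rose around a median of 0.46 (percentile 100), which was -0.13 with median centring. Against RPMI their median was -0.20 with Tuba1c (-1.48) lower, or 0.29 with median centring, and it lay within the random range there and with normexp fitted without dark spots. Both tubulin medians with SB202190, 0.46 and -0.20, were smaller in size than 0.5 of the -1.01 in EBSS. A shared EBSS or RPMI sample alone could give that among unrelated cultures of equal spread. Core histones H2B and H4, whose replication-dependent messengers lack long poly(A) tails, rose in EBSS, 10 of 13 of them, such as H2bc14 (2.10), H2bc4 (2.07) and H4c1 (1.58), with a median of 1.58 (percentile 100). Of these 5 fell with SB202190 against EBSS, including H4c1 (-1.30), while H2bc4 was at -0.20 (median -0.33, percentile 1.15), and 5 were higher with SB202190 against RPMI (median 0.47, percentile 100). Both histone medians with SB202190 were likewise smaller in size than 0.5 of the 1.58 in EBSS. Probes of both families can bind paralogs, so members are not separate measurements.

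Of 18 subunits of the vacuolar proton pump, some of them also in the lysosome list, 6 rose in EBSS, such as Atp6v1d (1.76), Atp6v1c1 (1.55) and Atp6v1a (1.46), with a median of 0.60 (percentile 99.99). With SB202190 against EBSS 5 fell, among them Atp6v1a (-1.53), with a median of -0.52 (percentile 0), and against RPMI the median was 0.09 (percentile 82.0) with 0 counted. Folliculin, its partners, Rag GTPases and Ragulator, which control the kinase mTORC1, had a median of 1.09 over 10 genes (percentile 100), with Fnip1 (2.67), Flcn (2.60), Fnip2 (2.41), Rragc (1.72) and Lamtor3 (1.62) higher. With SB202190 against EBSS Lamtor3 (-1.07), Rragc (-1.03) and Flcn (-1.02) fell (median -0.80, percentile 0), while Lamtor1 (-0.86 in EBSS, then 0.39) and Lamtor2 (-0.29, then 0.47) went the other way without being counted, and against RPMI 3 were higher (median 0.36, percentile 99.95). The 0.36 was under 0.5 of the 1.09 in EBSS, which the shared RPMI sample alone could carry over.

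Of 531 genes higher in EBSS, 192 were lower with SB202190, and of 336 lower genes 46 were higher. Array noise of the EBSS signal shared by both comparisons is argued against, since 202 genes still moved back with the changes taken from separate arrays, against 15.7 shared by independent lists. The EBSS culture or its RNA alone being out of line stays open: the median of EBSS with SB202190 against RPMI was 0.56 over the 531 genes and -0.83 over the 336, but the shared RPMI sample alone would carry over 0.68 and -0.62 between unrelated cultures of equal spread. A uniformly weaker starvation response with SB202190 also stays open: a first test on the spread around a common slope of 0.522 (SD 0.573 over 867 genes, highest of 100 simulations 0.113) set single cultures against technical noise. The mitosis list that replaced it had a median of -0.26 (percentile 0.1, or 2.73 with median centring) and not a positive one. This test could not decide. As 0 of its 33 members were counted as higher in EBSS, the list could hold 0 of the 192 moved-back genes. An effect of p38, of other targets of SB202190 or of a difference between single cultures could each account for the moved-back genes, and these were not tested.

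The rise of small nucleolar RNA host transcripts in EBSS with SB202190 may come from slower nonsense-mediated decay, which degrades many of them. Transcripts of 7 factors of this pathway, which it holds down in turn, had a median log2 ratio of 0.55 against RPMI (percentile 99.9), among them Smg5 (0.87) and Smg6 (0.66), while Upf1 (-0.02), Upf3b (0.01) and Upf2 (0.20) moved little and 0 of 7 were counted. The median lay where slower decay would put it, in a test chosen before these values were seen, but in EBSS against RPMI, where 7 of 16 host genes had risen, it was 0.45 and within the random range (percentile 96.6). With SB202190 against EBSS the median of the factors was 0.10 (percentile 76.8), so that an effect of the inhibitor itself on decay was not shown. Lower translation without amino acids, higher transcription of the host genes and a difference between cultures were not tested.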
